A study of Oryza sativa with 12 samples.

How the data were processed

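Total RNA from flag leaves and young emerged panicles of the rice lines KMR3 and IL50-7 was labelled with biotin and hybridised to 1-colour Affymetrix rice arrays, per the labels' protocols. The 12 arrays form 4 groups of 3, which the labels call biological replicates. Groups were taken from the line and organ that the labels state, and no 2 arrays held identical values.

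The authors deposited 1 linear intensity for each of 57381 probe sets and each array, from 0.01 to 21276. Version 1.2 of the GCOS software is named in the submitters' processing notes without its role. The algorithm, the scaling between arrays, the background correction and any filter are not given in the sources used here, nor is a genome build. Deposited trimmed means (2% trimmed at each end) ran from 125 to 296, a 2.38-fold range, and medians from 11.3 to 22.7.

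The plan written before the data were examined kept the submitters' scaling. Because of the range of array brightness, the arrays were instead quantile normalized, with control probe sets included. This was decided from the brightness of the arrays before any comparison was computed, and kept after counts of calls under 4 scalings had been seen, so counts on the deposited scale stand beside the main ones. The intensities were log2 transformed before normalization, and the normalized values were floored at the 10th percentile (log2 0.26). The 187 control probe sets were left out, and of the remaining 57194 probe sets the 34316 whose mean lay above the 40th percentile were kept. The 95th percentile of 23 control probe sets for unspiked transcripts gave a background of log2 4.01 (intensity 16.1). Where the 3 arrays of the dimmer group all lay below it, the fold is a lower bound against that background, and no fold is given where the brighter mean also lay below it. Where the dimmer mean but not every array of the group lay below it, levels are given instead of a fold.

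Probe sets were named through the supplied platform annotation and a RefSeq gene table (assembly ASM3414082v1), which was used only for names, chromosome numbers and gene order, because the build behind the array is not known. Of the probe sets 22436 have 1 gene, 95 several and 34663 none listed, and nothing was named from a probe set with several. All 17905 genes were found in the RefSeq table, and 2459 have a name other than a LOC number. List members carry the names used in the lists, so that MADS7, MADS8 and HSFA2A are listed there as AGL6, MADS24 and HSF11.

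Differences were tested with limma (version 3.58.1, R 4.3.3) in 1 model with 4 group means over all 12 arrays, so that the groups share a spread (8 residual and 3.22 prior degrees of freedom), with a trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. The contrasts were IL50-7 minus KMR3 in each organ, their difference, and panicle minus leaf in each line. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, using for each gene its brightest probe set and only lists with at least 5 tested members. Of 32 lists fixed before the data were examined, 21 name genes by locus, and 169 of their 302 entries were matched, through gene names. Most genes of the light-harvesting, starch synthesis and carbon fixation lists were not matched. Counts for these lists, in every comparison, cover a small part of each. The other lists rest on product names, which the tables used here lack. For that reason families recognisable from gene symbols were added. A longer set of them, which included families of called genes such as metallothioneins, was reduced to 7 after called genes had been seen and before any list result had been viewed.

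Named genes followed a rule written beforehand. For a line comparison it takes up to 10 called genes with the largest rise and up to 10 with the largest fall whose replicates do not overlap, or the 5 smallest p where fewer than 5 probe sets pass. For an organ comparison it takes 5 each way, for the interaction 5 each way, and for a list up to 4 called members with the largest change, or 2 where none passed. Genes named for their values on single arrays or behind a count at an unadjusted p were chosen after their values were seen. A named gene with several probe sets is represented by the brightest of those that passed in that comparison, and a list member by its brightest tested probe set. Called genes were placed in gene order, and the highest number in a window of 50 genes was compared with 10000 shuffles (Python 3.11.15, numpy 2.4.6).

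Alternatives changed 1 choice at a time: the filter (none, or the 60th percentile), the floor (none, or the 25th percentile), array medians set equal, no trend, array weights, the replicate number as a block, a fold minimum, only the 6 arrays of an organ, windows of 20 or 100 genes, the mean of a gene's probe sets, and each array left out in turn. A further 5 alternatives were added after the data had been seen. The method was tested on simulated values for the leaf comparison over 34316 probe sets. It recovered 52% of 100 probe sets changed by log2 1.5 and 86% of 100 changed by log2 3, with 6 false calls.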

Results

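Gene expression was measured in field-grown rice (Oryza sativa) of the lines KMR3 and IL50-7 on 12 Affymetrix rice arrays. IL50-7 is an introgression line, that is, a line carrying chromosome segments of a donor in the background of another parent, and the series title describes it as high yielding. Total RNA came from the flag leaf, the last leaf before the panicle, and from the young panicle after full emergence, with 3 biological replicates for each line and organ. Each array gave 1 intensity per probe set. In all 34316 probe sets were tested, of which 19874 map to 1 gene each (16491 genes). Trimmed mean intensities of the deposited arrays ran from 125 to 296, so all levels below are log2 intensities after quantile normalization. Across probe sets, which are not independent replicates, arrays of different organs correlated at r = 0.652 to 0.774. Replicate arrays of a group correlated at 0.896 to 0.961, and arrays of the 2 lines within an organ at 0.903 to 0.967, so line differences were of the size of replicate differences over the array as a whole. The number of arrays limits the precision of every value.

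The comparison of IL50-7 with KMR3 flag leaves asked which genes differ between the lines in the organ that supplies much of the grain's carbon. MT2C, a metallothionein of the metal-binding, cysteine-rich kind, was higher in IL50-7, at 12.74 ± 0.20 against 10.54 ± 0.75 (SD, n = 3 each), a 4.58-fold difference (limma, adjusted p = 0.0202), and 3 of its 4 other tested probe sets passed as well. MADS3, a C-class MADS-box gene of stamen and carpel identity, fell 4.99-fold, from 7.05 ± 0.53 in KMR3 to 4.73 ± 0.40 in IL50-7 (limma, adjusted p = 0.0267). MADS6, a floral MADS-box gene of the AGL6 kind, was also lower (log2 difference -2.40 ± 0.31 SE, limma adjusted p = 0.0203), and HAK4, of the potassium transporter family, was higher (3.01 ± 0.45, adjusted p = 0.04). Both line means of MADS6 and of HAK4 lay under the background of log2 4.01, so no fold is given for them. The largest rise was that of LOC4352177 on chromosome 12, at 4.59 ± 0.59 in KMR3, where 2 of 3 arrays lay above background, and 11.89 ± 0.85 in IL50-7, a 158-fold difference (limma, adjusted p = 0.00067). It has no other tested probe set. Rises and falls between the lines are differences in probe set intensity, and whether the probes match both lines equally was not tested.

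Among the genes without a descriptive symbol, LOC4350599 rose to 8.23 in IL50-7 leaves from a KMR3 mean of 1.91, under background, with 1 of the 3 KMR3 arrays above it. LOC9266870 rose at least 4.28-fold. LOC4337923 fell at least 26.5-fold, LOC4324961 fell 18.2-fold with 1 of 3 IL50-7 arrays above background, LOC4328294 at least 11.3-fold and LOC4329485 at least 7.67-fold. LOC4335011, at 11.71 ± 0.44 in KMR3 and 8.73 ± 0.44 in IL50-7 (SD, n = 3 each), was 7.91-fold lower (limma, adjusted p = 0.00067). LOC4325616, LOC4326745 and LOC4330873 were lower by 4.22-fold, 2.94-fold and 2.53-fold. Some of these genes have other tested probe sets. Of these, 1 of 2 passed with the same sign for LOC4350599, 0 of 2 for LOC4337923, 0 of 1 for LOC4328294 and 0 of 1 for LOC4325616. Folds given as "at least" are against the background. In all, limma called 25 probe sets at an adjusted p under 0.05, 10 higher and 15 lower in IL50-7, which belong to 15 genes and include 6 probe sets without a single listed gene. The unadjusted p was under 0.05 for 1665 probe sets, 4.85% of those tested, and the 3 values of each line did not overlap for 9.17%, where chance gives 10%.

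**Figure D1:**
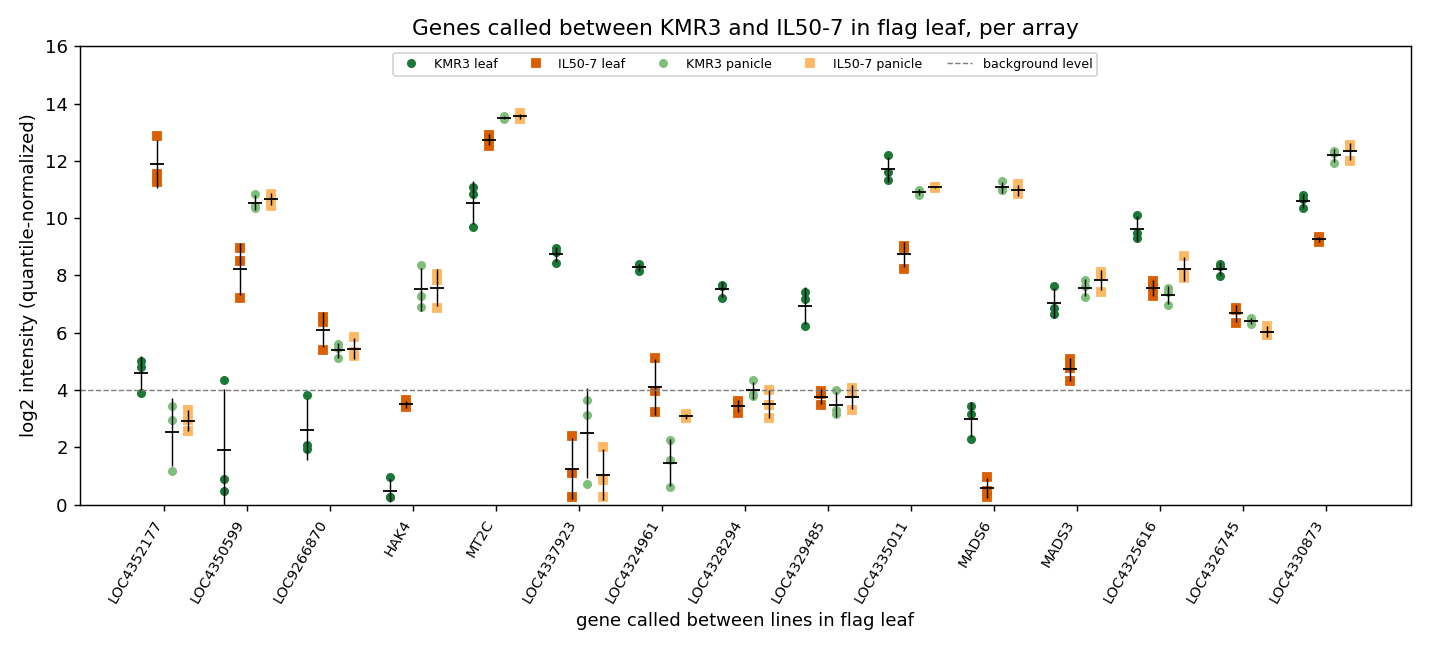
Log2 intensity, after quantile normalization, of the 15 genes called between flag leaves of KMR3 and IL50-7, in leaf and panicle, with 1 point per array, the mean and SD of the 3 arrays of each line and organ, and a dashed line at background (4.01). LOC4352177 stood at 4.59 in KMR3 leaves and 11.89 in IL50-7 leaves, and MADS6 and HAK4 lay below the dashed line in the leaves of both lines.

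Of the lists of genes fixed before the data were examined, the floral MADS-box list had 2 of 18 tested members past the test in leaves, MADS3 and MADS6, both lower in IL50-7 but MADS6 under background in both lines, and adjusted over the list alone it had the same count of 2. None of the 9 tested genes of grain yield and plant architecture passed (0 by limma over all probe sets and 0 adjusted over the list alone), with 1 at an unadjusted p under 0.05, SPL14 (-1.65 ± 0.73 SE). Light-harvesting and electron transport genes had 0 of 5 past the test and 0 at an unadjusted p under 0.05. Starch synthesis had 0 of 4, with 1 at an unadjusted p under 0.05, the starch synthase SSI (0.55 ± 0.22 SE). Most genes named in the light-harvesting and starch lists were not matched, so these counts do not speak for the pathways. The 12 tested genes of abscisic acid and drought response had a mean log2 difference of 0.47, with 0 called and a camera p of 0.0206 that became 0.237 after adjustment. Over fixed and added lists together 1 passed in leaves by camera, the added ribosomal proteins (adjusted p = 3.8e-07), a call lost with an estimated correlation (adjusted p = 0.815), and 4 did without IL50-7 leaf replicate 1.

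The leaf count moved from 25 to 84 without IL50-7 leaf replicate 1, to 11 without IL50-7 leaf replicate 2, to 13 without IL50-7 leaf replicate 3, to 16 without KMR3 panicle replicate 1, to 15 on the deposited scale or with a stricter filter on dim probe sets, and to 74 with array weights. With only the 6 leaf arrays 32 were called, 21 higher and 11 lower, of which 9 were among the 25, and 10 of the 15 named genes no longer passed. The share of called probe sets that were higher in IL50-7 was 40% here, 53.3% on the deposited scale and 52.4% with equal array medians. It was 82.4% without KMR3 leaf replicate 1, 69.6% without KMR3 leaf replicate 2 and 22.6% without IL50-7 leaf replicate 1. LOC4352177 and LOC4335011 stayed past the threshold in 26 of 26 alternatives. MT2C did in 20, MADS6 in 16, LOC4326745 in 14 and MADS3 in 12 of 26, LOC9266870 in 8 of 25 and HAK4 in 7 of 25. Over these alternatives the log2 difference of HAK4 ran from 1.46 to 3.71 and that of MADS6 from -2.77 to -0.93. The deviation of IL50-7 leaf replicate 1 from the other 5 leaf arrays correlated at 0.428 with the difference between panicle and leaf across probe sets, against -0.152 to 0.098 for each other leaf array. With KMR3 panicle replicate 3 and IL50-7 panicle replicate 2 left out, a pair chosen from its values, 59 leaf probe sets were called.

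In the emerged panicle the same comparison, under the labels as given, called no gene. The split that exchanges KMR3 panicle replicate 3 with IL50-7 panicle replicate 2, arrays in doubt from their values, called 678 probe sets. A count of 0 or a list mean near 0 under the labels therefore does not show that the lines are alike in panicles. LOC4352346, which was far higher in leaf than in panicle, had the smallest p of any probe set with a listed gene (adjusted p = 1 by limma). It stood at 4.38 in KMR3 panicles and at 1.41, under background, in IL50-7 panicles, so that the difference was at least 1.29-fold. Floral MADS-box genes had a mean log2 difference of 0.037 over 18 members, heat shock genes of -0.004 over 7, and cell cycle genes of -0.012 over 11, with 0 called in each. NIA1, a nitrate reductase, differed by -1.05 ± 0.41 SE and SUS5, a sucrose synthase, by -0.55 ± 0.23 SE, each with an adjusted p of 1. The other 4 of the 5 probe sets with the smallest p have no listed gene. By limma 0 probe sets passed and 1127 had an unadjusted p under 0.05, 3.28% of those tested, and 9.22% had lines that did not overlap, where chance gives 10%. On the deposited scale the count was also 0, while the median of all probe sets moved by -0.23, and it was 1 without IL50-7 panicle replicate 1 or replicate 2. Leaving out KMR3 panicle replicate 3 and IL50-7 panicle replicate 2, the pair chosen from its values, gave 128 probe sets, 53 higher and 75 lower in IL50-7, with 2803 at an unadjusted p under 0.05.

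Of the 25 probe sets called in leaves, 11 had the same sign in panicles, and 4 had an unadjusted p under 0.05 there, of which 0 had the same sign as in leaves. In the panicles of both lines 7 of the 25 lay under background, 1 of these 4 among them, so their signs there are not measured. Because no probe set passed in panicles, none could pass in both organs (0 by limma, with 1665 and 1127 at an unadjusted p under 0.05). Under the labels the line differences of leaf and panicle correlated at r = 0.03 across probe sets, which are not independent. With the same pair of panicle arrays left out, 22 probe sets passed in both organs with the same sign. Both arrays opposed the leaf state of their own line at 12 of 12 on or off probe sets, so leaving them out favours shared calls. The 22 are therefore no separate support for line effects shared by the organs.

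The interaction of line and organ, the panicle line difference minus that of the leaf, was past the threshold for 10 probe sets, 6 positive and 4 negative. A group mean lay under background for 6 of the 10. LOC4352177 had an interaction of -6.89 ± 0.84 SE (limma, adjusted p = 0.0329), being higher in IL50-7 by 7.30 in leaves, while the panicle means of both lines lay under background (2.52 and 2.93), so the size of its interaction is fitted, not measured. LOC4335011 had one of 3.15 ± 0.34 (adjusted p = 0.021), with line differences of -2.98 in leaves and 0.17 in panicles. For a probe set of MT2C it was -3.22 ± 0.43 (adjusted p = 0.0462), with line differences of 3.05 in leaves and -0.18 in panicles. Of the 4 other tested probe sets of MT2C, 0 passed for the interaction with the same sign. MADS3 and MADS6 did not pass (2.59 ± 0.46 and 2.29 ± 0.45 SE, adjusted p = 0.265 and 0.473), though both did when adjusted over the floral list alone, and MADS6 lay under background in the leaves of both lines. The count was 16 without IL50-7 leaf replicate 1, 6 without KMR3 leaf replicate 1, 4 without KMR3 leaf replicate 3 or KMR3 panicle replicate 3, 3 without IL50-7 leaf replicate 3, 2 without IL50-7 leaf replicate 2, and 1 without any 1 of the other 5 panicle arrays. It was 2 on the deposited scale and 3 without the pair of panicle arrays in doubt. With 1 array left out the share of positive calls ran from 33.3% (without KMR3 leaf replicate 1) to 100%. It was 60% here, 50% on the deposited scale, 30% with equal array medians and 100% with equal medians of the probe sets above the 80th percentile.

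The comparison of panicle with flag leaf, made within each line, set the organ labels against known organ genes. Chia1d, a chitinase, was at least 699-fold higher in the KMR3 panicle and at least 698-fold higher in that of IL50-7, and RTS, known for its expression in the tapetum that feeds developing pollen, was at least 863-fold and at least 711-fold higher. OSH1, a KNOX homeobox gene of shoot meristems, rose at least 195-fold in IL50-7 (limma, adjusted p = 6.65e-09). In the other direction CRSH2, of the family that makes the alarmone ppGpp in chloroplasts, was at least 227-fold lower in the KMR3 panicle (limma, adjusted p = 2.76e-06), and BURP2, of the BURP-domain family, fell from 12.44 to a mean of 3.24 in KMR3 and from 12.80 to 3.16 in IL50-7, both under background. LOC4351887 and LOC4352346 were at least 425-fold and at least 341-fold lower in the panicle of IL50-7.

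Of the 3' to 5' intensity ratios of control probe sets, a sign of RNA quality, that of GAPDH moved with organ and so with every list given for it. It was 2.54 to 6.32 in leaf arrays and 7.68 to 23.3 in panicle arrays. IL50-7 panicle replicates 1 and 3 had the lowest panicle ratios, at 8.72 and 7.68. The actin ratio overlapped between the organs, at 5.17 to 9.40 in leaf arrays and 4.95 to 13.4 in panicle arrays. Floral MADS-box genes were higher in the panicle as a group. In KMR3 16 of 18 rose, in IL50-7 17 rose, none fell, and adjusted over the list alone the counts were again 16 and 17. MADS7 and MADS8, of the E class of floral identity genes, rose at least 150-fold and at least 194-fold in KMR3 (limma, adjusted p = 1.21e-06 and 4.78e-07), MADS6 at least 135-fold, and MADS13, an ovule identity gene, at least 19.1-fold. The list passed by camera in both lines (adjusted p = 8.73e-08 and 1.11e-08) and with an estimated correlation (adjusted p = 0.00493 and 0.00338). All 7 heat shock genes rose in each line, and 7 did adjusted over the list alone. They were led by the heat shock factor HSFA2A (from 3.01, under background, to 13.40 in KMR3 and from 4.20 to 13.44 in IL50-7). Next by log2 difference came the chloroplast small heat shock protein HSP26.7 (9.25 ± 0.43 SE and 8.31 ± 0.43), HSP16.9A (7.10 ± 0.42 and 7.30 ± 0.42) and the disaggregase HSP101 (5.49 ± 0.17 and 5.34 ± 0.17). Camera gave that list an adjusted p of 3.33e-05 and 5.12e-05, and 0.0156 and 0.0176 with an estimated correlation.

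Anther, tapetum and pollen genes had 7 of 9 higher in the panicle in each line and 0 lower, and adjusted over the list alone 8 in KMR3 and 7 in IL50-7. C6, a lipid transfer protein of the tapetum, rose at least 475-fold in KMR3 and at least 222-fold in IL50-7, and the tapetal regulator TDR rose at least 17.0-fold in KMR3 and from 3.88, under background, to 8.09 in IL50-7. The lower C6 bound in IL50-7 came from panicle replicate 3, at 8.61 against 13.31 and 13.48 in replicates 1 and 2. The camera call of that list (adjusted p = 0.0134 and 0.0175) was lost with an estimated correlation (adjusted p = 0.47 and 0.515). RAFTIN1, another member of the anther list, stood at 11.06 in KMR3 panicle replicate 3 and 10.98 in IL50-7 panicle replicate 1, and between 4.92 and 7.77 in the other 4 panicles. Cell cycle and replication genes had 10 of 11 higher in each line, also adjusted over the list alone, with MCM4 and MCM5 of the replicative helicase up at least 9.25-fold and at least 15.2-fold in KMR3. Their camera call (adjusted p = 0.00127 and 0.00152) was lost with an estimated correlation (adjusted p = 0.266 and 0.27). In the cytokinin list 7 of 11 fell and 1 rose in KMR3, and 8 fell and 1 rose in IL50-7, with 8 and 8 lower adjusted over the list alone. CKX4, a cytokinin oxidase, fell 45.3-fold in KMR3, and the response regulators RR4 and RR9 fell 36.9-fold and 16.6-fold. That call too (adjusted p = 0.00158 and 0.00221) was lost with an estimated correlation (adjusted p = 0.266 and 0.27).

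Sucrose metabolism and transport had 10 of 15 members higher and 1 lower in each line, with the same counts adjusted over the list alone, and the sucrose synthase SUS3 rose at least 15.2-fold in KMR3 and at least 18.7-fold in IL50-7 (camera, adjusted p = 0.05003 and 0.0964). All 5 secondary wall genes rose in each line, also adjusted over the list alone, among them the cellulose synthases CESA4 (3.37 ± 0.78 SE), CESA7 (3.18 ± 0.63) and CESA9 (3.14 ± 0.54) in KMR3, with a camera adjusted p of 0.05003 and 0.0781. Light-harvesting and electron transport genes had 4 of 5 lower in KMR3 and 3 in IL50-7 (4 and 4 adjusted over the list alone), with the ferredoxin reductase FNR1 12.2-fold and 14.7-fold lower (camera, adjusted p = 0.0793 and 0.0846). NIA1 fell 57.9-fold in KMR3 and 126-fold in IL50-7, among 4 of 7 nitrogen assimilation genes that fell and 1 that rose in each line, the same adjusted over the list alone (camera, adjusted p = 0.159 and 0.146). SGR and NYC1, of chlorophyll breakdown, were 13.1-fold and 6.87-fold lower in the KMR3 panicle, among 4 of 4 tested in KMR3 and 3 of 4 in IL50-7, and adjusted over the list alone the counts were 4 and 3. The clock and flowering time list had 2 of 11 higher and 5 lower in KMR3 and 2 higher and 7 lower in IL50-7 (2 and 6, and 2 and 7, adjusted over the list alone), with the florigen gene Hd3a up from 3.17, under background, to 7.95 and the pseudo-response regulator PRR37 down 5.94-fold in KMR3. Its mean changed sign in KMR3 on the deposited scale (0.16, or 0.001 with equal array medians, against -0.21), and its camera call in IL50-7 (adjusted p = 0.0488) was lost with an estimated correlation (adjusted p = 0.515).

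**Figure D2:**
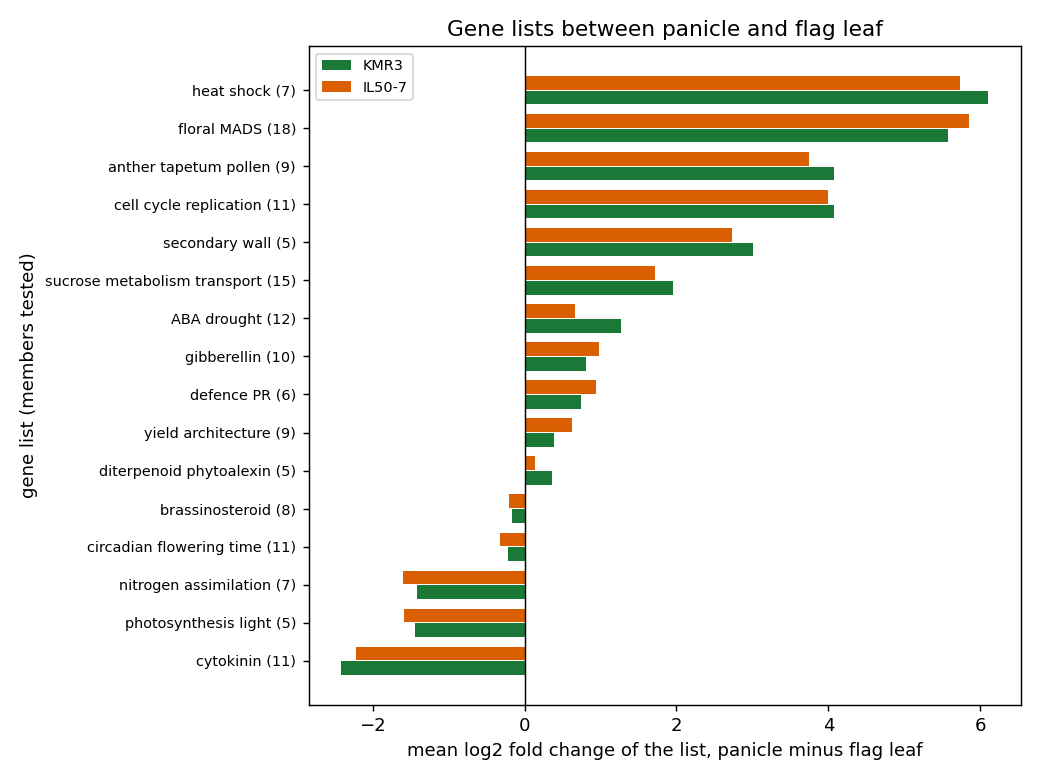
Mean log2 difference between panicle and flag leaf of the fixed lists with at least 5 tested members, for KMR3 and IL50-7. Floral MADS-box and heat shock genes lay furthest to the panicle side (5.57 and 6.10 in KMR3) and cytokinin genes furthest to the leaf side (-2.42 in KMR3); the means of the brassinosteroid list in both lines (-0.16 and -0.21) and of the clock list in KMR3 (-0.21) were above 0 on the deposited scale (0.36, 0.064 and 0.16) and, in KMR3, with equal array medians (0.19 and 0.001), and values of members under background are fitted, not bounds.

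Over all probe sets limma called 16314 between the organs in KMR3, 7727 higher and 8587 lower in the panicle, and 15635 in IL50-7, 7675 higher and 7960 lower. On the deposited scale the counts were 13065 for the organ difference in KMR3 and 11387 for the organ difference in IL50-7, and the median of all probe sets moved by 0.31 and 0.15 toward the panicle (-0.11 and -0.060 after normalization). The share of KMR3 calls higher in the panicle was 67.9% there and 59.99% with equal array medians, against 47.4% here, so changes are relative to the array's distribution. Without the pair of panicle arrays in doubt, 14135 and 13619 probe sets were called.

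Whether genes that differ between the lines lie side by side, which a line with introgressed segments raises as a question, was tested by placing the 15 genes called in either organ in gene order. With no panicle call, no gene could pass in both organs (0 by limma, with 1665 and 1127 probe sets at an unadjusted p under 0.05). The planned count of such genes per window was therefore 0 in advance. Of the called genes LOC9266870 and MT2C lay within a window of 50 genes on chromosome 5, and no window held more than 2, a number that shuffled positions reached with p = 0.462 (one-sided permutation test of 10000 shuffles). Chromosomes 1 and 2 held 4 called genes each and chromosome 5 held 3, with no chromosome past Fisher's exact test (lowest adjusted p = 0.776). Probe sets that were on or off between leaves of the lines, with a gap of at least log2 3, were placed as well, after the data had been seen. Of the 6 mapped genes on in IL50-7 leaves only, 5 lay on chromosome 12 (one-sided permutation p = 0.0008, adjusted p = 0.0024 over 6 sets), and of the 6 on in KMR3 leaves only, 3 did (permutation p = 0.158, adjusted p = 0.237). Without IL50-7 leaf replicate 1, up to 6 called genes lay in a window on chromosome 1 (permutation p = 0.0002), and with array weights 5 did (permutation p = 0.0004). Without the pair of panicle arrays in doubt, 6 of 97 called genes lay in a window on chromosome 12 (permutation p = 0.0009). That pair was in doubt partly for on or off probe sets whose mapped genes lie on chromosomes 12 and 1. The shuffles do not allow for that choice, so this p is no separate support for a cluster there.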

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

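Tests of KMR3 panicle replicate 3 and IL50-7 panicle replicate 2 on probe sets that are on or off, of KMR3 RNA in IL50-7 leaf replicate 1 and of a segregating segment were chosen only after the result was seen, as were the median criterion for panicle RNA, the rank correlations and the reading of the chromosome 1 and chromosome 2 results as undecided.

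The line difference itself differed between the organs for 10 probe sets, by limma's interaction term (adjusted p under 0.05). Of these values 4 rest on group means that all lay above background, those of MT2C, LOC4335011, LOC4325616 and 1 probe set without a listed gene (2.01), and the other 6 are fitted sizes. In LOC4352177 the panicle difference minus the leaf difference was -6.89, in a probe set of LOC4350599 it was -3.77 and in a probe set of MT2C -3.22, all 3 higher in IL50-7 leaves, with LOC4352177 under background in the panicles of both lines and LOC4350599 in KMR3 leaves. In LOC4324961 it was 5.80, in LOC4328294 3.58, in LOC4335011 3.15 and in LOC4325616 2.97, all 4 lower in IL50-7 leaves, with LOC4324961 and LOC4328294 under background in the panicles of both lines. In 3 probe sets without a listed gene it was 6.22, 2.01 and -5.36. Among other tested probe sets of these genes, 0 of 2 of LOC4350599 and 0 of 4 of MT2C passed for the interaction with the same sign. The same held for 0 of 1 of LOC4328294 and 0 of 1 of LOC4325616. Of 100 splits drawn from 200, 9 gave at least as many interaction calls as the 10 of the labelled split, the highest other 232, so chance cannot be excluded for that count. Of the 8 other splits among these 9, however, 7 grouped KMR3 panicle replicates 1 and 2 with IL50-7 panicle replicate 2, as did no other of the 100, which points to a structure of the samples, and the highest of the remaining splits was 19. The leaf, KMR3 organ and IL50-7 organ counts were 25, 16314 and 15635 with a highest other split of 2, 0 and 1 (1 of 10 splits each), and 10 splits are too few for a share under 0.05.

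No probe set was called between the lines in panicles, a count of 0 that any split reaches (10 of 10, so the splits say nothing). The split that exchanges KMR3 panicle replicate 3 with IL50-7 panicle replicate 2 called 678, which points to a structure of the samples, and of 328 panicle probe sets that were on or off 57 and 20 followed that split exactly and 0 the labels, while the commonest pattern, 185 off only in KMR3 panicle replicate 3 and IL50-7 panicle replicate 1 (the best correlated arrays, r = 0.967), follows neither, and the 3 other splits that keep that pair together called at most 1. All 12 probe sets that were on in the leaves of 1 line, off in those of the other, and on or off in panicles, with a gap of at least log2 3 and a bright state of at least 5.5 (4 on in KMR3 leaves, 8 in IL50-7 leaves) showed the other line's state in both KMR3 panicle replicate 3 and IL50-7 panicle replicate 2, 12 of 12, while the other 4 panicles showed their own. Above background on every array, 222 probe sets had a leaf line difference at an unadjusted p under 0.01, and most of these were not called. Over the 222, panicle differences under the exchange had the highest correlation of the 10 splits with the leaf differences (r = 0.698, rho = 0.635, r = 0.625 without the 10 largest). The labelled split had r = 0.52 and the next highest split 0.633. Splits are signed here with the side of KMR3 panicle replicate 1 taken as KMR3. With KMR3 panicle replicate 3 and IL50-7 panicle replicate 1 or 3 on that side, r was -0.563 and -0.573. With IL50-7 panicle replicate 2 and replicate 1 or 3 there, it was 0.633 and 0.569. A leaf line difference shared by the panicles would give each of these the opposite sign under the labels, and these signs under the exchange. By agreement of sign, however, the 167 of the exchange lay below 171 and 169 in other splits. The correlation is across probe sets, which are not independent. Exchanged labels of KMR3 panicle replicate 3 and IL50-7 panicle replicate 2 may account for the 57 and 20, which include the 12, but not for the 185. The mapped ones of the 12 lie on chromosomes 12 and 1 only. Mapped genes of the 57 lie on 5 chromosomes, with 28 of 36 on chromosome 2. Those of the 20 lie on 4, with at most 2 of 7 on the same chromosome. The 185 have mapped genes on 12 chromosomes, with 18 of 133 on the commonest. Segments that segregate within the lines stay open, but for the 57 and 20 they would have to lie on several chromosomes. A biological difference between the organs was not tested apart from them.

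IL50-7 leaf replicate 1 stood apart from its group, with 104 of 224 on or off leaf probe sets on in it alone and 47 on in it and KMR3 leaf replicate 2 only, whose cause was not tested. Of 35 probe sets on in the 3 KMR3 leaves and off in IL50-7 leaf replicates 2 and 3, it had 23 on and 12 off, and the 12 argue against KMR3 RNA as the whole source of the pattern. The 23 include 8 mapped genes, of which 4 lie on chromosome 1 (permutation p = 0.0577 over draws of equal size), so a chromosome segment that still segregates in IL50-7 could not be decided from so few genes. Without IL50-7 leaf replicate 1, 6 of 48 called genes lay in a window on chromosome 1 (permutation p = 0.0002). That window goes with such a segment, but its genes were not compared with these 4, so the question stays undecided. Of the 100 brightest panicle probe sets below background in the other 5 leaf arrays, 22 lay above background in it (4 to 9 for each other leaf array, treated likewise), between the bounds of 10 and 50 set beforehand, while the median of the 100 was 0.0315% of the panicle level, within the other arrays' -0.0174% to 0.0347%, which argues against panicle RNA mixed into it. A difference in stage or sampled tissue may remain, since 22 exceeds the other arrays and the design does not record it.

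On chromosome 2 lay 28 of the 36 mapped genes of 57 probe sets that were on in KMR3 panicle replicates 1 and 2 and IL50-7 panicle replicate 2 and off in the other 3 panicles (permutation p = 0.0001, the smallest the 10000 draws can give). If an IL50-7 segment lowers these genes, the leaf should show it: over the 54 probe sets above background in a leaf array the median leaf difference was -1.02, with 40 lower in IL50-7. This met the bound of -1 set beforehand by only 0.02, and the 30 probe sets on chromosome 2 alone had a median of -0.48, so the outcome was taken as undecided. Relative to the KMR3 leaves the medians were -0.27 in IL50-7 leaf replicate 1, -2.38 in replicate 2 and -1.81 in replicate 3. A segment carried only by some IL50-7 plants would leave KMR3 panicle replicate 3 on, which was off, so the pattern needs exchanged arrays or a difference among KMR3 plants as well, either of which could hold, and the -1.02 does not separate them.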

How the results depend on the processing

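Added after the data had been seen were the deposited scale, equal medians of the probe sets above the 80th percentile, and the 3 sets of arrays left out together. Counts of organ calls stayed within 1.5 times of 16314 and 15635 in every alternative except the replicate block, and no called named gene reversed its sign. Of the named genes' values under the alternatives 940 stayed on their side of the threshold, 235 were no longer past it and 3 came past it. The leaf calls were 15 with the filter at the 60th percentile (fewer probe sets tested), 74 with array weights, 15 as deposited, 59 without KMR3 panicle replicate 3 and IL50-7 panicle replicate 2, and 105 without KMR3 panicle replicate 3, IL50-7 panicle replicate 1 and IL50-7 leaf replicate 1. Panicle calls, 0 with 1127 at an unadjusted p under 0.05 by limma, were 1 without a filter, 128 without the first pair of arrays and 1 and 1 in the other exclusions. Calls in both organs went from 0 to 22 without the first pair. Its arrays opposed the leaf state of their own lines, so that choice favours shared calls. Interaction calls were 2 without a filter, 4 at the 60th percentile, 2 as deposited, 3 with those bright medians equal, and 3 and 3 without either pair. Lists past 0.05 moved from 1 to 2 (60th percentile) and 3 (3 arrays out) in leaf, from 0 to 3 (as deposited), 3 (first pair out), 1 and 1 (other exclusions) in panicle, and from 6 to 11 (as deposited) in the KMR3 organ comparison. The most genes in a window went from 2 to 5 with array weights, 6 without the first pair and 8 with 3 arrays out (permutation p = 0.0004, 0.0009 and 0.0001, the last the smallest that 10000 shuffles can give). These windows lay on chromosomes 1, 12 and 2. The first pair and the 3 arrays were chosen after their values had been seen, which the shuffles do not allow for. Leaving out each array in turn gave ranges of 11 to 84 leaf calls (84 without IL50-7 leaf replicate 1), 0 to 1 panicle calls, 1 to 16 interaction calls, 13737 to 17038 and 12939 to 16084 organ calls, 0 to 0 shared calls, 1 to 4 and 0 to 2 lists in leaf and panicle, 6 to 11 and 6 to 9 in the organ comparisons, and 1 to 6 genes in a window. The cause of these moves was not tested where none is given. Same-numbered arrays of the lines did not pair (correlations of deviations 0.018, -0.127 and 0.116 in leaf, -0.328, 0.40 and -0.248 in panicle), and not every array correlated best with its own number. With the replicate block the counts were 3 in leaf, 0 in panicle, 0 for the interaction, 7139 for the organ difference in KMR3 and 6740 for the organ difference in IL50-7. Signal over background limits dim genes: 27706 of the 34316 probe sets had a mean above it.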

Other observations

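The families named from gene symbols and the values of single arrays were chosen after the data were seen, and the other lists were fixed beforehand. Of the gibberellin, brassinosteroid and yield lists none passed camera between panicle and leaf, where 16314 of all 34316 probe sets were called in KMR3. In the gibberellin list 4 of 10 members rose and 1 fell in each line (4 and 5 higher, 1 lower in each, adjusted over the list alone), with the biosynthetic oxidase GA20ox3 up 6.39-fold in the KMR3 panicle and 9.47-fold in that of IL50-7, and GA20ox2 (SD1) down 4.14-fold and 4.29-fold. The brassinosteroid list had 2 of 8 higher and 4 lower in each line (2 and 3 higher, 4 lower in each, adjusted over the list alone). Its biosynthetic gene D11 fell 8.50-fold and 3.90-fold and its transcription factor BZR1 rose 4.95-fold and 2.06-fold, and its mean changed sign on the deposited scale in both lines and with equal array medians in KMR3 (0.19). The invertase gene GIF1 of the yield list rose from 2.35, under background, to 6.64 in KMR3 and at least 6.74-fold in IL50-7, and the flowering repressor DTH8 fell 8.45-fold and 7.21-fold, among 2 of 9 higher and 2 lower in KMR3 and 3 and 3 in IL50-7 (3 and 2, and 3 and 3, adjusted over the list alone). Camera gave adjusted p = 0.231 and 0.261 for gibberellin, 0.608 and 0.545 for brassinosteroid, and 0.968 and 0.921 for yield genes.

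Of abscisic acid and drought genes 4 of 12 rose in KMR3 and 3 in IL50-7 (4 and 3 adjusted over the list alone), LEA3 from 3.50, under background, to 7.87 in KMR3 and 15.6-fold in IL50-7 (camera, adjusted p = 0.30 and 0.852). Defence genes had 2 of 6 higher and 1 lower in KMR3 and 3 higher and 1 lower in IL50-7 (2 and 1, and 4 and 1, adjusted over the list alone; camera, adjusted p = 0.601 and 0.423), with WRKY71 up 7.33-fold and 5.59-fold. The phytoalexin list had 1 of 5 higher and 1 lower in KMR3 and 1 higher in IL50-7, the same adjusted over the list alone, with CYP99A3 down from 6.15 to 3.46, under background, in KMR3 (camera, adjusted p = 0.968 and 0.986). Wx, the granule-bound starch synthase gene, rose 32.2-fold and 28.0-fold, among 2 of 4 starch genes higher in KMR3 and 2 higher and 2 lower in IL50-7, the same adjusted over the list alone. Of 4 seed storage genes 2 fell in each line, also adjusted over the list alone, and of 2 carbon fixation genes 1 fell, RCA, by 2.12-fold and 2.08-fold (2 adjusted over the list alone). The kinase GSK2 was the single member of its list and did not pass in KMR3 (log2 difference 0.51) or IL50-7 (0.63), although adjusted over the list alone, that is unadjusted, 1 passed in IL50-7.

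Among the families added from gene symbols, 23 of 32 kinesins rose and 3 fell in KMR3, and 19 rose and 3 fell in IL50-7 (camera, adjusted p = 0.00127 and 0.00184; adjusted p = 0.47 and 0.515 with an estimated correlation). Expansins had 11 of 21 higher and 2 lower in each line (adjusted p = 0.0524 and 0.0964). Aux/IAA repressors had 11 of 24 higher and 3 lower in KMR3 and 15 and 4 in IL50-7 (adjusted p = 0.112 and 0.0964), and auxin response factors 7 of 17 higher and 1 lower in each (adjusted p = 0.0719 and 0.161). Laccases had 3 of 6 higher and 1 lower in KMR3 and 1 and 1 in IL50-7 (adjusted p = 0.608 and 0.986), and ethylene response factors 1 of 7 higher and 1 lower in KMR3 and 1 higher in IL50-7 (adjusted p = 0.659 and 0.876). Ribosomal protein genes had 2 of 22 higher and 1 lower in KMR3 and 8 and 1 in IL50-7 (adjusted p = 0.875 and 0.0846), with a KMR3 mean of 0.019 that was -0.007 with bright medians equal. In flag leaves the same 22 ribosomal protein genes had a mean line difference of -0.27 with 0 called by limma and 2 at an unadjusted p under 0.05; camera gave an adjusted p of 3.8e-07, and of 0.815 with an estimated correlation.

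The panicle deviations of KMR3 panicle replicate 3 and IL50-7 panicle replicate 1 correlated at 0.592 across probe sets. Of the 9 genes of the anther list, 7 were higher in both of these arrays than in each of the other 4 panicles. Among the 7, GAMYB stood in these arrays at 9.79 and 9.58 against 7.83 to 8.42 in the other 4 panicles, and EAT1 at 8.76 in both against 6.68 to 7.56. Of the remaining 2, PTC1 stood at 4.14 and 3.61 against 4.76 to 5.38, and C6 at 13.41 and 13.31 within the others' 8.61 to 13.48. The control probe set AFFX-Mgr-ef1a-3 had deposited intensities of 17.0 to 114 in leaf arrays and 0.79 to 15.3 in panicle arrays. The 17.0 was that of IL50-7 leaf replicate 1, and the next lowest leaf value was 56.7. Of the other Mgr control probe sets, gapdh-3 was also higher in every leaf array (2.56 to 15.2 against 0.51 to 1.60). The rest overlapped between the organs, such as ef1a-5 (3.17 to 11.5 in leaf arrays, 1.29 to 19.6 in panicle arrays).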
